A study of Mus musculus with 3 samples.

How the data were processed

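Total RNA of hippocampus tissue from wild-type C57BL/6 mice at postnatal day 14 was sequenced as paired-end reads of 150 bases on an Illumina NovaSeq, per the labels' protocols. The 3 libraries belong to 1 group. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript per 1000000 mapped fragments), with 1 column per library, per the file headers, and columns were matched to samples by the number in the sample titles. Reads were mapped with Bowtie2 to GRCm38 (mm10), per the submitters' processing notes. The counting tool, the gene annotation and all versions are not given in the sources used here, nor is whether counting used strand. How reads shared by gene copies were assigned is also not given, so values of paralogs, pseudogenes, repeated sequences and overlapping or antisense genes are uncertain.

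The table held 39377 rows with gene symbols and Entrez identifiers, of which 20331 were at 0 in all libraries and 13337 had a mean of at least 1 FPKM. Of the identifiers, 36506 were found in the RefSeq gene table of GRCm38.p6, used for coordinates and biotypes. GENCODE M21, on the same assembly, gave transcript lengths and GC content by gene symbol. FPKM were used as deposited, without further scaling. A value of 0 can be a failed estimate, so such genes are described as listed at 0 and given per library.

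Depth was estimated because low FPKM values step by whole fragments. For genes with 1 annotated transcript of at least 800 bases, the worth of 1 fragment and the number of bases taken off the transcript length were chosen so that values came out as whole fragments. Values equal to at most 4 fragments were then within 0.15 of a whole number in 93.0%, 91.7% and 90.7% of cases in libraries 1, 2 and 3, where evenly spread values without fitting would give 30%. Both settings were chosen on these same values, so 30% is not the level without signal after fitting. The estimates were 3690040 fragments (95% bootstrap interval 3682910 to 3717470), 4201680 (4184100 to 4219410) and 5917160 (5917160 to 5988020), from 100 draws. The worth of 1 fragment was searched on a grid, so the intervals partly reflect the grid steps and the last digits carry no precision. A level of 3 fragments for a transcript of 2 kb was 0.467, 0.410 and 0.290 FPKM. Fragment numbers and floors cover counting error only, since reads without molecular identifiers are not independent molecules. This estimate was added after the data were seen.

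Levels were compared as log2(FPKM + 1), a scale that understates differences of low genes. For each gene with a mean of at least 1 FPKM, the difference to Slc22a17 was formed in each library and tested with limma 3.58.1 in R 4.3.3 against a null of at most 1 log2 unit (its treat function, two-sided), with Benjamini-Hochberg adjustment and calls at adjusted p under 0.05. The 2-fold null was chosen because FPKM of different genes also differ by length, GC content and mappability. Adjustment was repeated over each list alone, and among all lists only the astrocyte list changed, from 4 to 3 lower genes. Pairs of genes were tested with limma's moderated test of the difference, against a null of no difference and adjusted over 26 pairs, and ratios are means of the ratios per library. An exact sign-flip test of 3 libraries cannot go below p = 0.25 and was not used. On simulated values for 13336 genes compared with Slc22a17, the test called 100% of 50 genes at a true log2 difference of -3, 90% at -2, 12% at -1.5 and 84% at 2, and 3 of 13136 genes within the null. Nearly all simulated genes lay within the null, whereas in the data 12183 of 13336 genes were called lower and 210 higher. The adjustment was therefore stricter in the simulation, and its rates of calls do not carry over to the data.

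In total 29 gene lists with 307 different genes and the 26 pairs were fixed before the data were examined, from general knowledge of iron metabolism, hippocampal cell types, neighbouring tissues and stress responses. List levels were compared with 10000 random lists of the same size. Deviations of a library were compared with 10000 random lists matched on mean expression in 20 bins, which treat genes as independent although genes of 1 cell type vary together. On simulated deviations over 13337 genes, 49 of 50 lists of 10 genes shifted by 0.5 log2 units and 1 of 50 unshifted lists passed the 95th percentile. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

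The genes named in the text were set by a rule fixed before the data were examined: Slc22a17, the 10 solute carrier genes and the 10 genes overall with the highest means (mitochondrially encoded ones apart), the 3 highest members of each list, every member of the Slc22, lipocalin, iron and ferroptosis lists, every gene of the pairs, and the 10 genes with the largest SD of log2(FPKM + 1) among those at a mean of at least 5 FPKM. Slc3a2 is also a member of the ferroptosis list. The mitochondrial ribosomal RNAs, Xist and genes named in the closing part outside this rule were chosen after their values were seen. Some genes that the rule takes are counted in the totals but not reported by name here.

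The alternatives tried were a pseudocount of 0.1 FPKM, no filter or a filter at a mean of 5 FPKM, a null of no difference, rescaling each library to a sum of 1000000, quantile normalisation, another background for list levels and leaving out each replicate in turn. No count model was used, since the values are not counts. No comparison between conditions was made, since the samples form 1 group.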

Results

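RNA-seq was carried out on whole hippocampus of wild-type C57BL/6 mice at postnatal day 14, a stage at which the dentate gyrus is still adding granule neurons. The samples formed 1 group of 3 libraries of total RNA from mixed cell types, here called libraries 1, 2 and 3. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. With 1 group there was no condition to compare, and the comparisons were made between genes inside the same libraries, for Slc22a17, the gene named in the title of the series, and for iron handling and postnatal neurogenesis, which the title also names. Estimated from the steps between low FPKM values, depth was about 3690040, 4201680 and 5917160 fragments in libraries 1, 2 and 3. Values after ± are SDs over n = 3 libraries unless an SE is named, and FPKM of different genes also differ through transcript length, GC content and mappability.

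Slc22a17, which encodes a cell-surface receptor described for lipocalin-2, was among the abundant transcripts of the tissue. Its level was 216, 195 and 208 FPKM in the 3 libraries, with a mean of 206 ± 10.8 FPKM (SD, n = 3) and a coefficient of variation of 5.23%. It ranked 500 by mean among the 19046 genes above 0 in at least 1 library, at the 97.4th percentile. The gene (Entrez 59049) lies on the minus strand of chromosome 14 from 54906727 to 54913132 in GRCm38, and the protein-coding transcript used for its fragment numbers has 9 exons and 2294 bases. The number of other annotated genes overlapping this span was 0 in both RefSeq and GENCODE. The value rested on about 1623, 1665 and 2516 fragments, for a counting error of 2.48%, 2.45% and 1.99%.

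Against every other gene with a mean of at least 1 FPKM, 12183 of 13336 were lower than Slc22a17 by more than 2-fold, 210 were higher by more than 2-fold, and 943 were not called (limma test against a null of at most 1 log2 unit, Benjamini-Hochberg adjusted). Among the most abundant were Tmsb4x, which encodes an actin-sequestering peptide, at 4458 ± 309 FPKM, and Apoe, the main lipid carrier of astrocytes, at 3958 ± 167 FPKM. The translation factor gene Eef1a1 reached 3205 ± 67.7 FPKM, the tubulin gene Tuba1a 3009 ± 186 FPKM, and the ribosomal protein gene Rplp1 3088 ± 296 FPKM. Apoe stood 4.26 log2 units above Slc22a17 (SE 0.104). The remaining rows of the top 10 were small RNAs and predicted genes: Bc1 at 124074, 179412 and 0 FPKM in libraries 1, 2 and 3, Gm10925 at 17985 ± 867 FPKM, Gm10222 at 4885, 4843 and 1407 FPKM, and Rn7s1 and Rn7s2, whose values were identical at 3378 ± 99.4 FPKM. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, ranked apart, stood at 6662 ± 1079 and 4578 ± 513 FPKM. Values of Eef1a1, Tuba1a, Rplp1, Tmsb4x, Rn7s1, Rn7s2 and the predicted genes are uncertain because near-identical copies can share their reads. Gm10925 is a pseudogene in RefSeq whose synonyms are those of a mitochondrially encoded protein gene, so it is not known whether its value counts reads of that gene. With a null of no difference in place of a 2-fold one, the number of higher genes was 408. Since 12183 of 13336 genes were lower, a high count of lower genes in a list is close to what all genes give.

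Within the Slc22 family of organic ion transporters, Slc22a17 made up 89.0% ± 0.571 (SD, n = 3) of the summed FPKM of the 25 members. The next member was Slc22a23, at 9.71 ± 0.963 FPKM, 4.28 log2 units below Slc22a17 (SE 0.0972). Slc22a8, the organic anion transporter 3 gene, stood at 4.13 ± 0.887 FPKM, and the carnitine and ergothioneine transporter genes Slc22a5 and Slc22a4 at 3.47 ± 0.186 and 3.99 ± 0.727 FPKM. Slc22a15 was at 1.65 ± 0.0551 FPKM. These 5 members were the ones that reached a mean of 1 FPKM, and 5 of 5 were lower than Slc22a17 by more than 2-fold, both over all genes and adjusted over the list alone (limma, Benjamini-Hochberg; the highest adjusted p, of Slc22a23, was 6.53e-07; lower in 3 of 3 libraries). Over all genes 12183 of 13336 were lower, so this count by itself does not set the family apart. A further 8 members were above 0 in at least 1 library but under 1 FPKM on average, among them Slc22a21 at 0.75 ± 0.380, Slc22a6 at 0.633 ± 0.241 and Slc22a3 at 0.53 ± 0.131 FPKM. Slc22a18 was listed at 0, 0.39 and 0.41 FPKM, Slc22a12 at 0, 0 and 0.48, Slc22a7 at 0.23, 0.21 and 0, Slc22a2 at 0, 0 and 0.20, and Slc22a16 at 0, 0.12 and 0. The other 11 members were listed at 0 in all 3 libraries. For a transcript of 2 kb, 3 fragments corresponded to 0.467, 0.410 and 0.290 FPKM, so the values under 1 FPKM rested on few fragments.

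**Figure D1:**
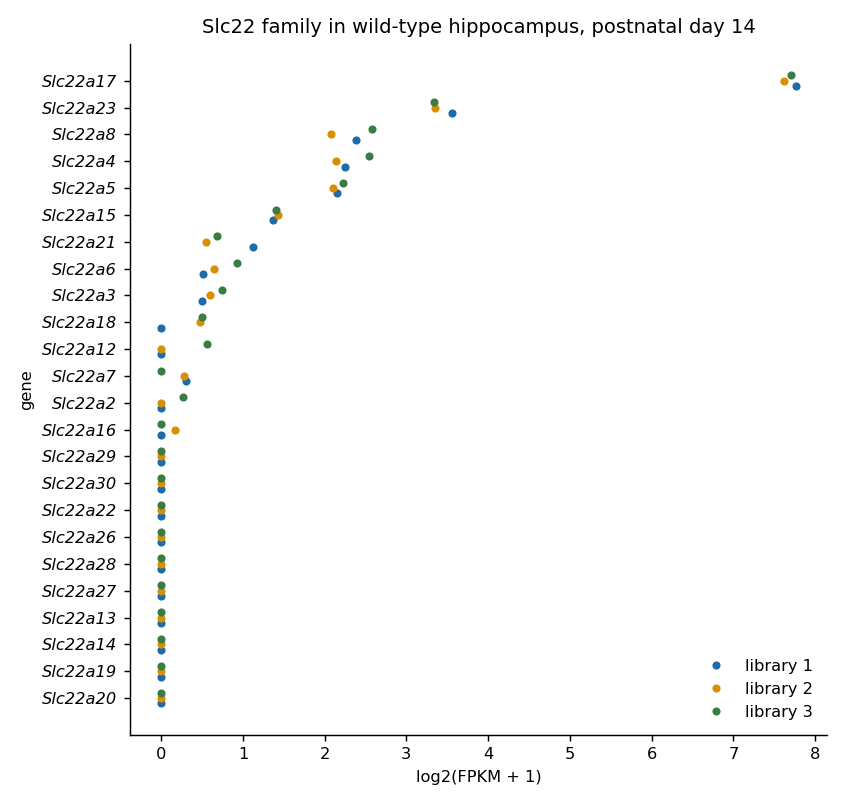
Level of 24 of the 25 Slc22 family members as log2(FPKM + 1), 1 row per gene and 1 point per library (n = 3). Slc22a17, at a mean of 206 FPKM, stands apart from Slc22a23 at 9.71 FPKM, and 10 of the members drawn lie at 0 in all libraries.

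Solute carrier genes were taken by symbol, as those starting with Slc and a digit, without a check of what each encodes. Across these genes, Slc22a17 ranked 7 of 378 in each of the 3 libraries and carried 3.18% ± 0.145 of their summed FPKM. The mitochondrial ADP/ATP carrier gene Slc25a4 was the highest at 634 ± 14.2 FPKM. It was followed by Slc17a7, the vesicular glutamate transporter 1 gene, at 452 ± 38.6 FPKM, and Slc25a3, the mitochondrial phosphate carrier gene, at 408 ± 10.5 FPKM. The glial glutamate transporter genes Slc1a2 and Slc1a3 stood at 401 ± 69.0 and 324 ± 13.2 FPKM, and the ADP/ATP carrier gene Slc25a5 at 358 ± 2.18 FPKM. Below Slc22a17 came Slc25a23, an ATP-Mg/phosphate carrier gene, at 134 ± 12.7 FPKM, and the mitochondrial glutamate carrier gene Slc25a22 at 129 ± 7.54 FPKM. Of the 229 solute carrier genes tested, 219 were lower than Slc22a17 by more than 2-fold and 1 was higher, Slc25a4, by 1.62 log2 units (SE 0.0968; limma adjusted p = 0.000702; higher in 3 of 3 libraries). The other 9 were not called, among them Slc17a7, Slc25a3, Slc1a2, Slc25a5, Slc1a3, Slc25a23, Slc25a22 and Slc3a2, so their distance from Slc22a17 was not shown to exceed 2-fold. With a null of no difference, 6 solute carrier genes were higher. The count of 219 of 229 lower genes lies near the share over all genes, 12183 of 13336. Slc25a4, Slc25a3 and Slc25a5 have processed pseudogenes that can share reads.

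**Figure D2:**
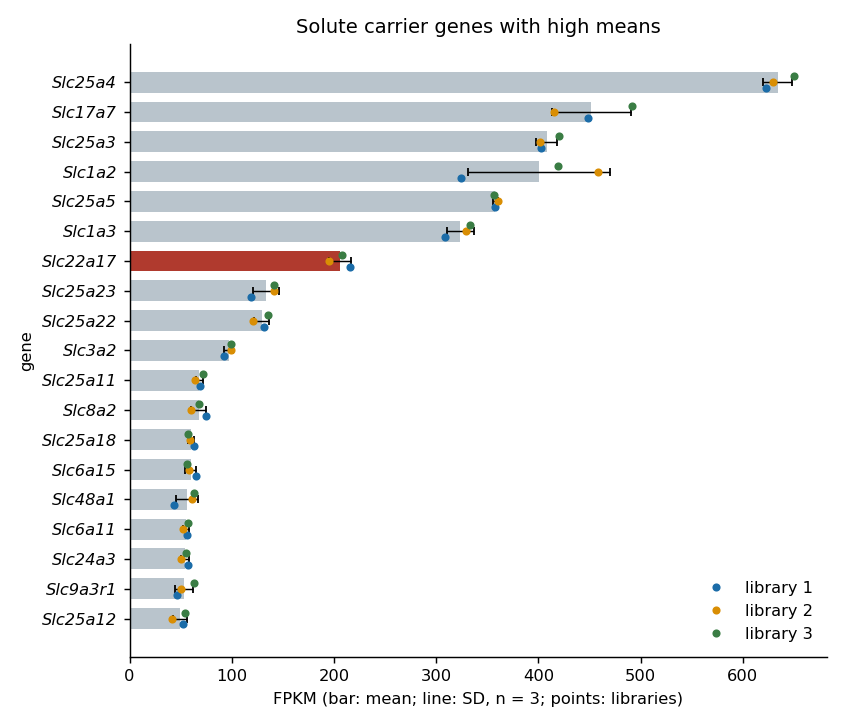
Mean FPKM of 19 of the 20 solute carrier genes with the highest means (bars), with the SD over n = 3 libraries (lines) and each library (points). Slc22a17, in red at 206 FPKM, follows Slc1a3 at 324 FPKM and precedes Slc25a23 at 134 FPKM.

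For lipocalin-2 and the receptors proposed for it, Slc22a17 was the abundant member. Lcn2, the gene of the siderophore-binding ligand itself, was at 0.41, 1.08 and 0.51 FPKM, and Lrp2, which encodes megalin, at 0.02, 0.05 and 0.03 FPKM. The melanocortin receptor gene Mc4r stood at 1.40 ± 0.305 FPKM, Mc3r was listed at 0, 0 and 0.14 FPKM, and Mc1r at 0 in all 3 libraries. Bdh2, whose product has been linked to a mammalian siderophore, was at 1.86 ± 0.882 FPKM. The 2 members tested, Mc4r and Bdh2, were both lower than Slc22a17 by more than 2-fold, over all genes and adjusted over the list alone. The values of Lcn2, Lrp2 and Mc3r lay near or under the level of a few fragments, so their order was not resolved at this depth.

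Among iron genes, the ferritin subunits were the highest. Fth1, the heavy chain gene, stood at 2350 ± 225 FPKM and Ftl1, the light chain gene, at 1036 ± 134 FPKM, which placed them 3.5 (SE 0.115) and 2.32 (SE 0.122) log2 units above Slc22a17. The glutathione peroxidase gene Gpx4, which protects membrane lipids from peroxidation, was at 559 ± 51.0 FPKM and 1.43 log2 units above (SE 0.118). These 3 genes were called higher than Slc22a17 by more than 2-fold, in 3 of 3 libraries each (limma adjusted p = 2.55e-06, 6.00e-05 and 0.00751). Over the lipocalin, iron and ferroptosis lists together, 48 of 54 genes tested were lower, 3 were higher and 3 were not called, and the counts adjusted over the list alone were again 48 lower and 3 higher. Over all genes 12183 of 13336 were lower. The counts of lower genes here and in the single lists below are near that share and do not set iron genes apart. The 3 not called were the iron chaperone gene Pcbp2 at 152 ± 20.9 FPKM, the iron-sulphur scaffold gene Iscu at 89.8 ± 10 FPKM and the amino acid transporter heavy chain gene Slc3a2 at 96.9 ± 4.14 FPKM. Fth1 and Ftl1 have many pseudogenes, and their values are uncertain to that extent. The call of Pcbp1 (82.3 ± 7.0 FPKM, 1 of the 48 lower genes, adjusted p = 0.0127) was lost without replicate 1 (adjusted p = 0.0506), and Iscu (adjusted p = 0.0933) passed without replicate 2 (adjusted p = 0.0371).

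Genes of iron uptake were all lower than Slc22a17 where tested, 11 of 11. The transferrin receptor gene Tfrc led them at 28.1 ± 3.60 FPKM, followed by Trf, the transferrin gene, at 16.8 ± 3.32 FPKM. Slc11a2, which encodes the divalent metal transporter 1, was at 7.62 ± 0.488 FPKM, Tfr2 at 5.80 ± 0.816 FPKM, Slc39a14 at 5.39 ± 0.787 FPKM, Slc39a8 at 4.01 ± 0.222 FPKM and Hfe at 3.96 ± 0.484 FPKM. The ferrireductase genes Steap3 and Steap2 stood at 2.66 ± 0.438 and 2.25 ± 0.210 FPKM, Slc11a1 at 2.57 ± 1.37 FPKM, and Steap1 was listed at 0, 1.46 and 1.73 FPKM. Scara5 was at 0.577 ± 0.168 FPKM, Cubn at 0.0467 ± 0.0208 FPKM, and Steap4 was listed at 0, 0.08 and 0.06 FPKM.

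In iron storage and export, 6 of 9 tested genes were lower than Slc22a17. Besides the ferritins and the Pcbp genes, Ncoa4, the ferritinophagy receptor gene, was at 45.1 ± 1.46 FPKM. Slc40a1, which encodes the iron exporter ferroportin, was at 8.28 ± 0.691 FPKM, the heme exporter gene Flvcr1 at 4.75 ± 1.02 FPKM, and the ferroxidase genes Cp and Heph at 3.52 ± 1.35 and 1.77 ± 0.214 FPKM. Ftmt and Hephl1 were listed at 0 in all 3 libraries.

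In iron regulation, 7 of 7 tested genes were lower. Fbxl5, the iron-sensing ubiquitin ligase subunit gene, stood at 42.0 ± 4.53 FPKM, Epas1 at 29.8 ± 3.5 FPKM, Neo1 at 23.8 ± 3.72 FPKM and Hif1a at 16.5 ± 0.792 FPKM. The iron regulatory protein genes Ireb2 and Aco1 were at 15.9 ± 0.547 and 12 ± 0.123 FPKM. Bmp6 was at 2.32 ± 0.880 FPKM and Bmp2 at 0.547 ± 0.176 FPKM, while Hamp, the hepcidin gene, and Tmprss6 were listed at 0 in all 3 libraries. Hjv was not analysed here.

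In mitochondrial iron and heme metabolism, 13 of 14 genes were lower and Iscu was not called. Hmox2, the constitutive heme oxygenase gene, was at 55.5 ± 7.58 FPKM and the inducible Hmox1 at 4.42 ± 0.492 FPKM. Glrx5 stood at 53.2 ± 5.50 FPKM, Alas1 at 34.8 ± 7.29 FPKM, Fech at 28.2 ± 3.60 FPKM, Nfs1 at 26.3 ± 4.04 FPKM, Abcb8 at 20.8 ± 4.05 FPKM, and the biliverdin reductase genes Blvra and Blvrb at 17.1 ± 2.18 and 13.6 ± 2.47 FPKM. The mitoferrin genes Slc25a28 and Slc25a37 were at 8.94 ± 0.993 and 1.68 ± 0.516 FPKM.

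In the ferroptosis list, 9 of 11 tested genes were lower, Gpx4 was higher and Slc3a2 was not called. Slc7a11, the cystine transporter gene, was at 4.30 ± 0.130 FPKM and Aifm2, which encodes the ferroptosis suppressor protein 1, at 3.93 ± 1.36 FPKM. Acsl4 stood at 19.4 ± 1.88 FPKM, Keap1 at 17.0 ± 0.811 FPKM, Dhodh at 15.1 ± 3.06 FPKM, Lpcat3 at 13.8 ± 1.85 FPKM and Nfe2l2 at 7.21 ± 0.937 FPKM. Ptgs2 and Chac1 were at 3.5 ± 1.02 and 3.44 ± 0.950 FPKM, Alox5 at 0.617 ± 0.215 FPKM, Gch1 at 0.567 ± 0.203 FPKM, and Alox15 was listed at 0.13, 0 and 0 FPKM.

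**Figure D3:**
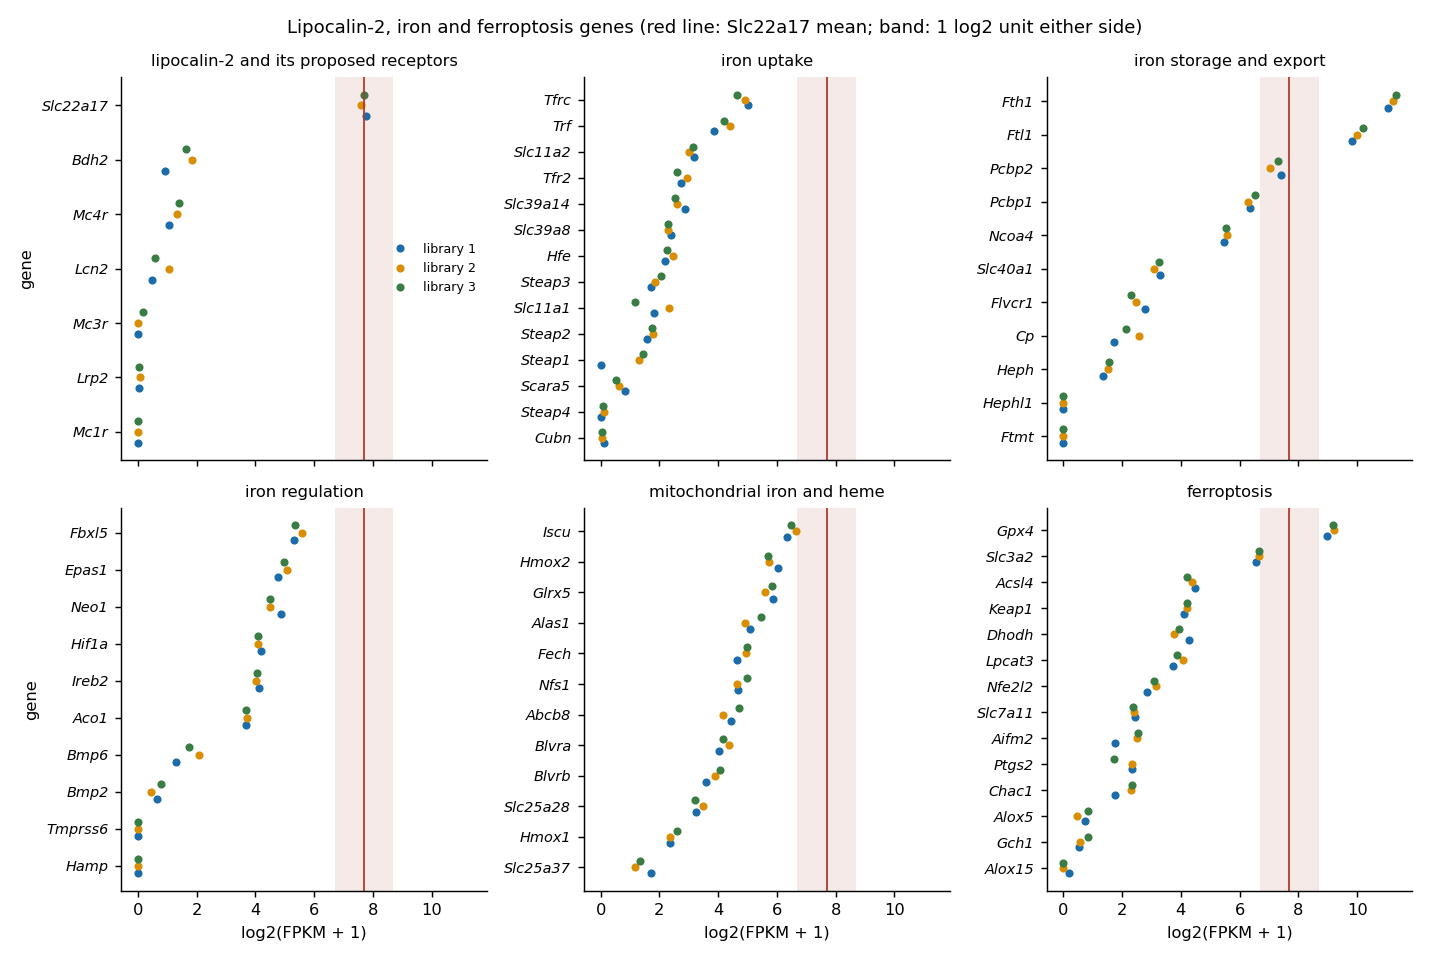
Level of the members reported here of the 6 lipocalin, iron and ferroptosis lists as log2(FPKM + 1), 1 point per library (n = 3), with the Slc22a17 mean as a red line and 1 log2 unit either side as a band. Fth1 (2350 FPKM), Ftl1 (1036 FPKM) and Gpx4 (559 FPKM) lie above the band, and Tfrc (28.1 FPKM) and Slc40a1 (8.28 FPKM) lie below it.

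Pairs of related iron genes, fixed before the data were examined, were compared in FPKM. Fth1 was 2.28 ± 0.0893 times Ftl1 (SD, n = 3). Tfrc was 3.70 ± 0.545 times Slc11a2 and 3.41 ± 0.512 times Slc40a1. Gpx4 was 130 ± 14.8 times Slc7a11 and 154 ± 50.8 times Aifm2, and Hmox2 was 12.7 ± 2.78 times Hmox1. Slc25a28 was 5.71 ± 2.09 times Slc25a37, Pcbp2 1.85 ± 0.226 times Pcbp1, Ireb2 1.33 ± 0.0576 times Aco1, Slc39a14 1.34 ± 0.120 times Slc39a8 and Cp 1.96 ± 0.620 times Heph. Each of these differences passed a limma moderated test over the 26 pairs (Benjamini-Hochberg, adjusted p at most 0.0194), with the same sign in 3 of 3 libraries. The differences of Ireb2 from Aco1, Slc39a14 from Slc39a8, Pcbp2 from Pcbp1 and Cp from Heph were under 2-fold, a size that transcript length, GC content and mappability can also give. Steap3 was 1.18 ± 0.137 times Steap2, which was not called (adjusted p = 0.143). The call of Slc39a8 against Slc39a14 was lost when any replicate was left out (adjusted p 0.0801, 0.0780 and 0.0508), and that of Heph against Cp without replicate 3 (adjusted p = 0.0806).

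Pairs of neuronal and glial genes compared markers of stages and cell types and related genes. The tissue was mixed and the cells behind each value were not measured, so the ratios are not ratios of cells or stages. Dcx, the doublecortin gene of migrating immature neurons, was 8.93 ± 2.64 times Eomes, the gene of intermediate progenitors (SD, n = 3). The mature neuron gene Rbfox3 was 5.39 ± 0.921 times Dcx, and Calb1, a marker of mature granule cells, 3.85 ± 0.879 times Dcx. Calb2, which immature granule cells and interneurons express, was 1.88 ± 0.368 times Calb1. Prox1, the granule lineage gene, was 7.34 ± 1.78 times Eomes. Sox4 was 2.58 ± 0.145 times Sox11, Ccnd2 3.89 ± 0.30 times Ccnd1, and Neurod2 1.78 ± 0.370 times Neurod1. Slc12a5, the chloride exporter gene of maturing neurons, was 7.0 ± 0.142 times the chloride importer gene Slc12a2. The glutamate receptor subunit gene Grin2a was 1.47 ± 0.366 times Grin2b. The myelin gene Mbp was 31.3 ± 5.35 times the precursor gene Pdgfra, Slc17a7 was 8.83 ± 2.10 times Gad1, and Gad1 was 3.31 ± 0.935 times Gad2. The differences of Calb2 from Calb1, Neurod2 from Neurod1 and Grin2a from Grin2b were likewise under 2-fold. In all, 25 of the 26 preset pairs passed the limma test, with the same sign in 3 of 3 libraries. That test asked only whether the FPKM of the 2 genes were equal. Transcript length, GC content and mappability can make them unequal, so passing it does not by itself show a difference in transcript number. The call of Neurod1 against Neurod2 was lost without replicate 2 (adjusted p = 0.0592) and that of Grin2a against Grin2b without replicate 2 or replicate 3 (adjusted p 0.0828 and 0.0735).

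The preset cell type lists gave levels of genes in a mixed tissue. Which cells expressed each member was not measured, so the levels are not shares of cells or stages. In the list of neuroblasts and immature neurons, 14 of 14 members were at 1 FPKM or more in all libraries, with a median of 34.8 ± 6.61 FPKM (SD, n = 3) and with the cytoskeletal genes Stmn1 (723 ± 24.9 FPKM), Stmn2 (687 ± 62.0 FPKM) and Tubb3 (307 ± 45.6 FPKM) highest. All 14 had their highest value in library 1. Radial glia and neural stem cell genes had a median of 8.59 ± 0.612 FPKM, led by Fabp7 at 797 ± 56.7, Hopx at 184 ± 12.1 and Vim at 54.4 ± 11.9 FPKM, which astrocytes also express. Genes of dividing cells and intermediate progenitors had a median of 2.36 ± 0.417 FPKM, with Pcna at 52.9 ± 2.82, Ccnd2 at 38.4 ± 3.27 and Ccnd1 at 9.90 ± 0.694 FPKM. This list lay at percentile 23.3 of random lists of the same size drawn from genes above 0, which does not set it apart. Dentate granule neuron genes had a median of 9.87 ± 1.45 FPKM, led by Rbfox3 at 63.4 ± 3.73, a gene of neurons in general, Calb1 at 44.8 ± 0.897 and C1ql3 at 27.8 ± 4.55 FPKM. Genes of the pyramidal CA fields had a median of 17.5 ± 5.35 FPKM, with Pcp4 at 446 ± 17.9, Bok at 84.4 ± 13.1 and Mpped1 at 61.2 ± 8.52 FPKM.

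Excitatory synapse genes had a median of 133 ± 14.2 FPKM (SD, n = 3), with Nrgn at 1099 ± 15.8, Camk2a at 820 ± 91.1 and Snap25 at 781 ± 66.9 FPKM. GABAergic neuron genes had a median of 21.4 ± 1.65 FPKM, with the neuropeptide genes Cck at 804 ± 95.2, Sst at 712 ± 83.4 and Npy at 208 ± 24.6 FPKM. Of the same list, Gad1 and Gad2 stood at 52.45 ± 8.16 and 16.3 ± 3.11 FPKM. Whether cells other than GABAergic neurons gave part of the Cck value was not tested. Astrocyte genes had the highest median of the lists, 156 ± 7.31 FPKM, led by Aldoc at 592 ± 62.6 FPKM, Slc1a2 and Slc1a3. Myelinating oligodendrocyte genes had a median of 52.1 ± 3.45 FPKM, with Mbp at 716 ± 49.8 and Cnp at 90.7 ± 7.66 FPKM, against 16.5 ± 1.36 FPKM for their precursors, with Olig1 at 96.6 ± 13.4, Pdgfra at 23.2 ± 3.72 and Gpr17 at 21.1 ± 1.08 FPKM. Microglial genes had a median of 27.0 ± 1.76 FPKM, with C1qa at 52.2 ± 7.24 and C1qc at 49.1 ± 5.44 FPKM. Endothelial and pericyte genes had a median of 5.92 ± 0.365 FPKM, with Rgs5 at 64.9 ± 7.29, Cldn5 at 54.0 ± 1.64 and Vtn at 36.5 ± 3.98 FPKM. Against random lists of the same size drawn from genes above 0, 10 of the 28 lists lay above the 95th percentile: excitatory synapse, astrocytes, myelinating oligodendrocytes, immature neurons, red blood cells, iron storage and export, microglia, mitochondrial iron and heme, GABAergic neurons and CA fields. Members at 0 in all libraries were left out of that percentile. For iron storage and export this left 9 of 11 members, without Ftmt and Hephl1. Their middle value was Ncoa4 at 45.1 FPKM, against a median of 8.28 FPKM over all 11. The dentate granule list, with 11 members and a median of 9.89 FPKM over the gene means, lay at percentile 84.1. The high place of iron storage and export therefore depends on leaving those members out. Against genes with a mean of at least 1 FPKM only, 6 lists lay above the 95th percentile, iron storage and export again without those members. The 4 that did not were microglia (percentile 94.9), mitochondrial iron and heme (90.2), GABAergic neurons (89.9) and CA fields (84.9).

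**Figure D4:**
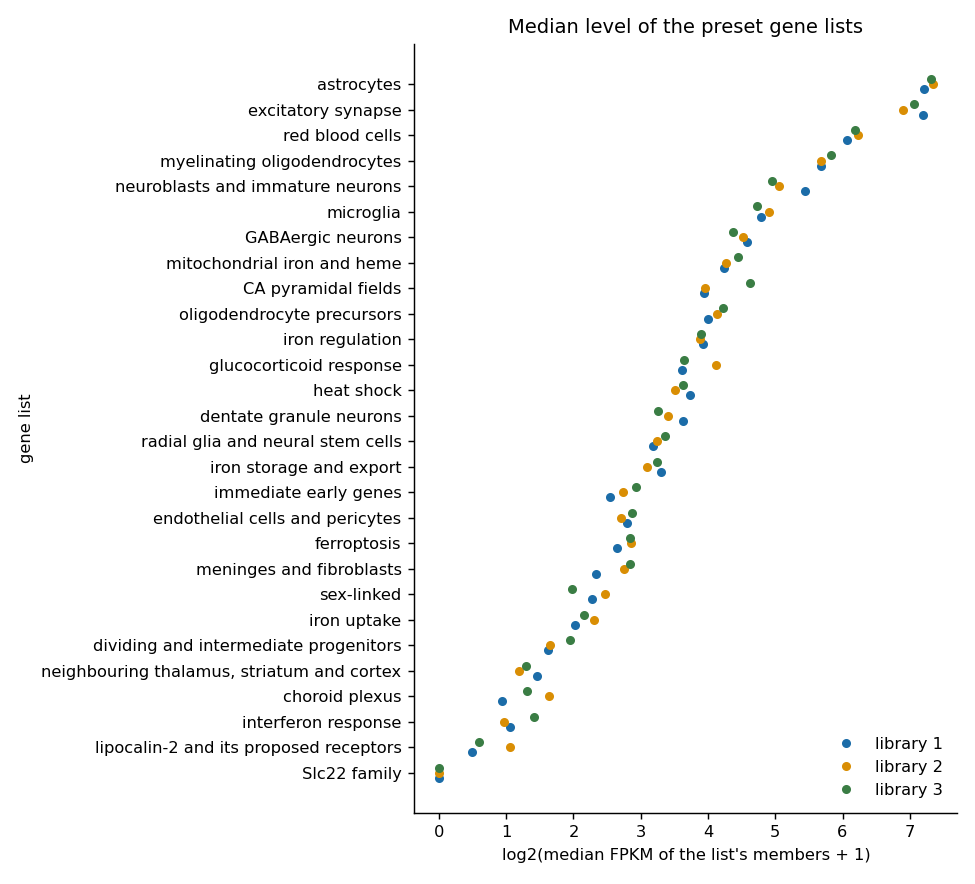
Median FPKM of the members of each preset list, as log2(median FPKM + 1), 1 point per library (n = 3). Astrocytes (156 FPKM) and excitatory synapse (133 FPKM) lie highest and the Slc22 family lowest, at 0.

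Lists for neighbouring tissue and for the state of the tissue were measured in the same way. Red blood cell genes had a median of 70.7 ± 4.28 FPKM (SD, n = 3), with Hbb-bs at 569 ± 79.6, Hba-a2 at 255 ± 17.7 and Hba-a1 at 103 ± 4.63 FPKM, where near-identical paralogs can share reads. Genes of meninges and fibroblasts had a median of 5.31 ± 1.12 FPKM, with Dcn at 42.0 ± 7.15, Col1a2 at 7.31 ± 1.77 and Col3a1 at 6.15 ± 0.290 FPKM. Markers of neighbouring thalamus, striatum and cortex had a median of 1.5 ± 0.239 FPKM, with Fezf2 at 16.0 ± 0.801, Prkcd at 12.5 ± 1.68 and Ppp1r1b at 11.2 ± 1.62 FPKM. Immediate early genes had a median of 5.70 ± 0.910 FPKM, with Junb at 11.2 ± 1.13, Egr1 at 9.72 ± 0.987 and Nr4a1 at 8.84 ± 1.61 FPKM. Glucocorticoid-responsive genes had a median of 13.1 ± 2.86 FPKM, with Tsc22d3 at 60.5 ± 13.6, Sgk1 at 31.0 ± 0.995 and Fkbp5 at 14.5 ± 4.93 FPKM. Heat shock genes had a median of 11.3 ± 0.943 FPKM, with Hspa8 at 763 ± 68.6, Hsph1 at 47.1 ± 11.4 and Dnajb1 at 18.6 ± 0.457 FPKM. Interferon-responsive genes had a median of 1.24 ± 0.378 FPKM, with Bst2 at 10.2 ± 1.43 and Isg15 at 2.10 ± 0.548 FPKM. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were above 0 in all 3 libraries, at 29.6 ± 6.26, 14.0 ± 1.38 and 3.77 ± 0.777 FPKM, while Xist was listed at 0, 0.26 and 0.01 FPKM. Of the list of 13 mitochondrially encoded protein genes, 0 were tested, and their levels were not analysed here.

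Among the preset lists, the 3 libraries differed most in genes of the choroid plexus, the secretory tissue next to the hippocampus. Ttr, its transthyretin gene, was at 392 FPKM in library 1, 1071 in library 2 and 1296 in library 3, Folr1 at 3.25, 7.08 and 9.16 FPKM, and Aqp1 at 0.91, 2.21 and 3.33 FPKM. The list had a median of 1.5 ± 0.600 FPKM (SD, n = 3), and its 7 members with a mean of at least 1 FPKM were lowest in library 1, with a median deviation of -0.64 log2 units from the mean of the libraries. Immature neuron genes went the other way: 14 of 14 were highest in library 1, with a median deviation of 0.24 log2 units, as for Dcx at 14.9, 11.5 and 9.71 FPKM and Neurod1 at 29.3, 16.4 and 15.1 FPKM. Among 10000 random lists matched on expression, the choroid plexus deviation lay at percentile 0 and the immature neuron deviation at percentile 100. Microglial genes were also low in library 1 (median deviation -0.16, percentile 0.22), and glucocorticoid-responsive genes were low in library 1 (-0.29, percentile 0.06) and high in library 2 (0.24, percentile 99.8). Dentate granule genes were low in library 3 (-0.17, percentile 0.81) and heat shock genes in library 2 (-0.20, percentile 0.88). Immature neuron genes lay at -0.10 in library 3 (percentile 0.88) and -0.09 in library 2 (percentile 1.75), the counterpart of their deviation in library 1. Of the 84 list and library combinations, 8 lay below the 1st or above the 99th percentile. The deviations of each gene sum to 0 over the libraries, so these 8 are not independent.

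**Figure D5:**
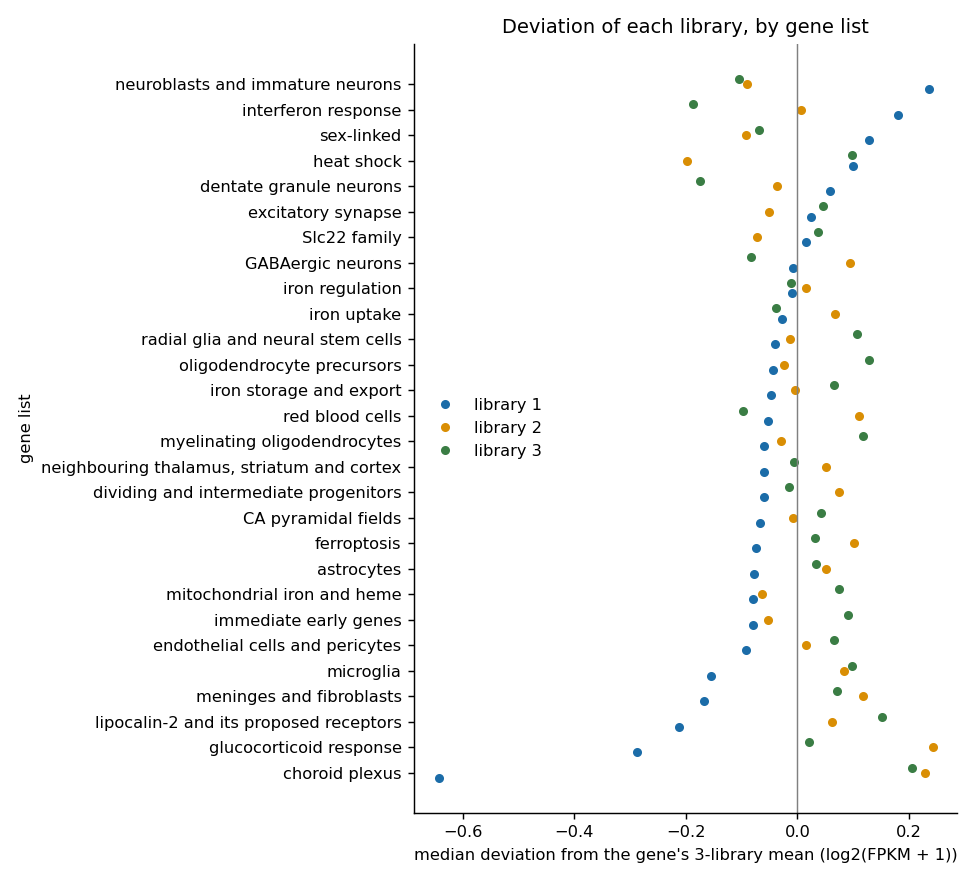
Median deviation of each library from the gene means, in log2(FPKM + 1) units, over the members of each preset list with a mean of at least 1 FPKM (n = 3 libraries). Library 1 lies at -0.64 for choroid plexus and at 0.24 for immature neurons.

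Most single genes varied little between the libraries. The median SD of log2(FPKM + 1) was 0.175 over 13337 genes, and 1753 genes (13.1%) had a highest value at least 2 times the lowest. Pearson's r across genes was 0.967 to 0.971 for the 3 pairs of libraries, where genes are not independent replicates. The 10 genes with the largest spread among those at a mean of at least 5 FPKM were non-coding RNA or pseudogene transcripts, each listed at 0 in at least 1 library. After Bc1 they were Gm14303 at 0, 205 and 1119 FPKM, Gm6565 at 0, 107 and 0, Gm23472 and Gm23444 each at 0, 62.5 and 85.3, Snhg9 at 73.0, 0 and 52.9, Snora73b at 0, 0 and 56.1, Rpl14-ps1 at 90.2, 0 and 16.3, Gm10241 at 64.1, 33.7 and 0, and Gm26316 at 0, 41.8 and 34.1 FPKM. Bc1 alone made up 16.7%, 21.9% and 0% of the summed FPKM of libraries 1, 2 and 3. The count of genes with a ratio of at least 2 fell to 415 for genes at a mean of at least 5 FPKM, and was 879, 967 and 1081 without replicate 1, 2 and 3.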

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

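Rescaling without Bc1 was chosen after seeing the data. With a null of no difference in place of a 2-fold one, 408 genes and 6 solute carrier genes were higher than Slc22a17, against 210 and 1, since a smaller difference then suffices. With no filter on low values, 13 Slc22 family members were lower in place of 5, since more genes are tested. Against a background of genes with a mean of at least 1 FPKM, 6 lists in place of 10 lay above the 95th percentile, since that background is higher. The count of genes with a ratio of at least 2 between libraries was 415 for a mean of at least 5 FPKM and 6605 with no filter, against 1753, and ran from 879 to 1081 when 1 replicate was left out, since 2 libraries span a smaller range. Rescaling to a sum of 1000000 gave a median SD of 0.247 in place of 0.175, and 0.186 without Bc1. All other counts against Slc22a17 stayed within 1.5 times under each alternative run. Of 59 named Slc22, lipocalin, iron and ferroptosis genes, 59 were on the same side of the threshold with a pseudocount of 0.1 FPKM, rescaled, with no filter and without replicate 3, 58 without replicate 1 or 2, and 56 with a null of no difference. Of the 26 pairs, 26 were on the same side with the other pseudocount and with rescaling, 25 without replicate 1, and 23 without replicate 2 or 3, and the cause was not tested. At about 3690040 to 5917160 fragments, levels under 0.467 FPKM rest on fewer than 3 fragments of a 2 kb transcript in library 1, and such genes cannot be ordered.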

Other observations

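Receptor, transporter and peptide genes outside the preset lists were grouped after their values were seen and are given as levels only. Gabra5, a GABA receptor subunit gene of hippocampal pyramidal cells, was the highest of the glutamate and GABA receptor subunits reported here at 141 ± 5.80 FPKM (SD, n = 3), above Gria1 at 93.8 ± 9.45, Grin1 at 70.1 ± 10.6 and Gria2 at 67.1 ± 14.5 FPKM. Among NMDA receptor subunits, Grin3a stood at 8.13 ± 0.398, Grin2c at 7.92 ± 1.34, Grin2a at 6.18 ± 0.352, Grin2d at 5.6 ± 0.396 and Grin2b at 4.33 ± 0.844 FPKM, and among kainate receptor subunits Grik5 led at 50.1 ± 4.74 FPKM. Of the vesicular transmitter transporters, Slc17a7 at 452 ± 38.6 FPKM exceeded Slc32a1, which loads GABA, at 22.9 ± 2.54 FPKM and Slc17a6 at 6.61 ± 1.54 FPKM.

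Among zinc transporters, Slc39a7 was at 44.9 ± 3.16 FPKM and Slc30a9 at 39.9 ± 2.17 FPKM (SD, n = 3), above Slc30a3, which fills synaptic vesicles with zinc, at 18.9 ± 3.86 FPKM. Among neuropeptide genes beyond Cck, Sst and Npy, Cort was at 53.9 ± 16.4, Tac1 at 39.9 ± 4.47, Vip at 14.1 ± 1.39, Pdyn at 10.2 ± 2.00 and Penk at 10.1 ± 4.52 FPKM. AY036118 and Lars2 varied together, at 3506 and 420 FPKM in library 1, 466 and 58.6 in library 2 and 2300 and 294 in library 3, with a ratio of 8.04 ± 0.284. Whether reads of repeated sequences gave these values was not tested, so the ratio does not show that the 2 genes are expressed together.

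The patterns weighed here were noticed in these data. The tests on short transcripts, shared copies, the depth behind Bc1 and all neurons were chosen after their results, or the values behind them, had been seen, while the second gene lists and the bounds for scaling and for length and GC content were written before. The length and GC test was first run on the longest transcript of any kind and changed to the longest protein-coding one after that result was seen. Explanations by cell or tissue composition were tested within the libraries, but none that rests on a difference between groups, since the design has 1 group.

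In all, 22 genes had a mean of at least 5 FPKM but were listed at 0 in 1 or 2 libraries, the largest being Bc1 at 124074, 179412 and 0 FPKM. Too few fragments in library 3 are argued against for Bc1, because that library had the most, about 5917160 against 3690040 and 4201680. Of the 20 with a RefSeq entry, 10 are not pseudogenes, and 8 of these (80.0%) are annotated at 300 bases or less, against 9 of 9071 other genes at that level, and a candidate explanation is that FPKM becomes unstable when a transcript is about as long as a sequenced fragment. Pseudogenes made up the other 10 of the 20 against 93 of 9164 others (Fisher's exact test, two-sided, odds ratio 97.5, p = 3.39e-15), so reads shared with near-identical copies may account for these, and for some short genes too, since Gm23444 and Gm23472 had identical values and Snora73a (27.6, 0 and 0 FPKM) and Snora73b (0, 0 and 56.1) are paralogs, so length and shared reads are not separated there. Rescaling by the column sum lets Bc1 move all other genes, as the median SD of 0.247 with it and 0.186 without it shows.

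Choroid plexus genes were lower in library 1, with a median log2 ratio to the mean of libraries 2 and 3 of -0.96 over 7 genes. A scaling difference is argued against by the median over all 13337 genes, 0.016, and a trend with transcript length or GC content by the 99.8% of the list's median that remained after its removal (103% with the longest transcript of any kind). Less choroid plexus tissue in the dissection may account for it, but a second list of 15 choroid plexus genes had a median of only -0.10, at percentile 12 of matched random lists. That lay between the bounds set beforehand, below 5 for this explanation and 25 or above against it, so it stays open. In the second list 9 genes were lower in library 1 and 6 were higher, as for Enpp2 at 32.5, 42.9 and 63.8 FPKM on the one side and Car12 at 8.5, 7.03 and 6.91 and Cab39l at 16.8, 12.7 and 13.7 FPKM on the other.

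Immature neuron genes were higher in library 1, with a median log2 ratio of 0.36 over 14 genes. A larger share of all neurons is argued against by the 22 excitatory synapse and GABAergic genes, whose median was -0.0062 with an SD of 0.30 between members. A trend with length or GC content is argued against by the 82.4% of the median that remained (86.0% with the longest transcript of any kind). A second list of 18 immature neuron genes had a median of 0.18, at percentile 100 of 10000 matched random lists and 99.98 of another draw of 10000, with 14 of 18 highest in library 1, as for Tubb2b at 767, 614 and 681 FPKM and Cd24a at 80.0, 57.1 and 67.1 FPKM. A larger share of immature neurons in library 1 may account for this, and what would have set such a share was not tested.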
